A study of Mus musculus with 10 samples.

How the data were processed

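RNA from 10 samples of mouse small intestine organoids was measured on 10 single-colour arrays, 5 from cultures with TNF and PEG vehicle and 5 from cultures with TNF and pegtarazimod. Groups and replicate numbers were taken from the sample labels. Per the labels' protocols, total RNA was isolated with a column kit, amplified to cDNA and labelled with biotin with a whole-transcript kit. The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with the package oligo and the RMA method, which corrects background, normalises by quantiles between arrays and summarises probes per probe set. Versions, the annotation and the genome build are not given in the sources used here, and no coordinates are therefore printed. Because quantile normalisation makes the distributions of all arrays nearly alike, a change common to most genes would not be visible in these values. The concentrations of pegtarazimod (mg/ml) and of the PEG vehicle (mM) are given in different units, and whether they hold the same amount of PEG is not given in the sources used here.

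The deposited table held 22203 probe sets. A platform annotation gave 1 gene symbol for 19572 of them and several for 0, and 2631 were unnamed here and were left out of the main tests. All 19572 gene identifiers matched the GRCm38.p6 gene table, which was used for names only and changed 0 symbols. Of the resulting 19505 genes, 55 had several probe sets and were represented by the one with the highest mean over all arrays. No gene had probe sets that differed in opposite directions, each at an unadjusted limma p below 0.05. No detection or background calls were used, so a value near the low end of an array cannot be told from background and a fold against it may be understated. Correlations between arrays over all genes were 0.989 to 0.994 within vehicle, 0.983 to 0.992 within pegtarazimod and 0.974 to 0.991 between groups, and at most 3 genes had identical values in any pair of arrays, so no array was counted as a copy of another.

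Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates), and p-values were adjusted by the Benjamini-Hochberg method over 19505 genes, with 0.05 as the threshold. Differences are pegtarazimod minus vehicle. Lists of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over 35 lists. The lists, the tests, the alternatives and the rule for the genes named were set before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among genes past the threshold whose groups did not overlap, up to 4 members of each described list with the smallest p, and 15 single genes, of which 13 were measured under a symbol here (Olfm4 and C3 were not). Genes of a list that moved against the rest of it and fell outside this rule were named after their values were seen. In Mt1, Mt2, Cyp, Ces2, Ugt, Clca and defensin families, probes may take up signal from close relatives.

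The test was checked on simulated arrays with the means of 19505 genes and their spreads as moderated by limma. Of the genes, 200 outside the lists were changed, and the 22 genes of the enterocyte list were shifted by 0.5 besides. Among the 200, it recovered 45 of 67 genes changed by 0.5 on the log2 scale, 67 of 67 changed by 1 and 66 of 66 changed by 2, with none in the wrong direction. Of 192 calls 11 were false (5.73%), and of the 35 lists 1 was called, the one that had been shifted by 0.5. The simulated genes were independent and held no difference between replicates 1 and 2 and replicates 3 to 5, so this check does not tell how often lists are falsely called on the real arrays. Moderated spreads are drawn towards a common value, so recovery and false calls of genes may also differ on the real arrays.

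Alternatives were quantile normalisation over all 19505 genes, centring of each array on its median, leaving out the dimmest 25% or the dimmest 50% of genes, an intensity trend with robust priors, array weights, a block for the replicate number, a block for replicates 1 and 2 against 3 to 5, the mean over the probe sets of a gene, and leaving out each array in turn. Fits within replicates 1 and 2 and within replicates 3 to 5, from a model with 4 groups that pooled the spread, were added after the data were seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.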

Results

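The expression of 19505 genes was measured on 10 single-colour arrays hybridised with RNA from BALB/c mouse small intestine organoids, which are self-organising cultures of intestinal epithelium. All organoids received 20 ng/ml recombinant mouse TNF for 48 h. In 5 cultures the TNF was combined with 5 mg/ml pegtarazimod, a PEG-linked peptide known as an inhibitor of classical complement activation and of myeloperoxidase. The other 5 cultures received 2.625 mM PEG as vehicle. The series design describes the 5 samples of each group as biological replicates, but the sources used here do not state what differed between them. Array medians lay between 5.48 and 5.53 on the log2 scale, and single values between 1.88 and 12.97. Precision was limited by the number of arrays. No cultures without TNF were analysed here, so every difference is one between pegtarazimod and vehicle in the presence of TNF.

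The comparison addressed which transcripts pegtarazimod altered in TNF-treated epithelium. With pegtarazimod, 8 of 22 enterocyte genes, 9 of 18 fatty acid oxidation genes and PPAR targets and 6 of 18 goblet cell genes rose, and 12 of 17 stem cell genes, 7 of 15 Wnt targets, 9 of 17 Paneth cell genes (8 of 16 with genes of identical values counted once) and 13 of 37 NF-kB response genes fell. These 7 lists were shifted by camera with a preset correlation, and none kept its call with an estimated correlation (adjusted p = 0.0575 to 0.169). The metallothionein gene Mt2 was 14.1-fold lower, the NADPH oxidase gene Nox1 9.48-fold lower (to a dim level that makes its fold uncertain) and the Tnf transcript 6.54-fold lower, whereas the fatty acid binding protein gene Fabp1 was 5.55-fold higher. By limma with Benjamini-Hochberg adjustment, 954 genes changed, of which 488 were higher and 466 lower, and 155 of them changed at least 2-fold (84 higher and 71 lower). The values of the groups did not overlap for 1309 genes, 6.71% of those tested against 0.794% given by chance. The number of changed genes was 437 without vehicle 3, 498 without vehicle 4, 562 without vehicle 5, 552 without pegtarazimod 1 and 522 without pegtarazimod 2.

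Within each group, replicates 1 and 2 stood apart from replicates 3 to 5. The principal component that held 33.4% of the variance left after the group means were removed placed vehicle 1 and 2 at -13.5 and -12.0 and the other vehicle arrays between 8.20 and 9.02, and pegtarazimod 1 and 2 at -27.6 and -19.0 and the others between 11.4 and 21.2. The labels name no batch, and the values reported are from a fit without a term for this split, so for the shifted lists the means within the 2 subsets stand beside them. Pegtarazimod changed 1229 genes within replicates 1 and 2 and 651 within replicates 3 to 5, at a spread pooled over all 10 arrays. Of these, 392 changed in both subsets in the same direction and 1 in opposite directions. With the 2 subsets as a block, 1820 genes changed. Of 115 named genes that passed over the 10 arrays, 70 passed in both subsets, 20 in replicates 1 and 2 alone, 14 in replicates 3 to 5 alone and 11 in neither (Casp1, Cox6c, Dll1, Fas, Hk2, Krt19, Oas1a, Sdha, Serpinb6a, Top2a, Txn1), at fewer arrays per difference. All 954 genes that changed over the 10 arrays had the same direction in both subsets, and 627 of them had the larger difference in replicates 1 and 2. The difference over the 10 arrays averages those of the subsets, so choosing genes by it favours like directions. Mt2 differed by -4.16 in replicates 1 and 2 and by -3.58 in replicates 3 to 5, Nox1 by -2.51 and -3.73, Tnf by -3.60 and -2.12, and Fabp1 by 3.33 and 1.90.

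**Figure D1:**
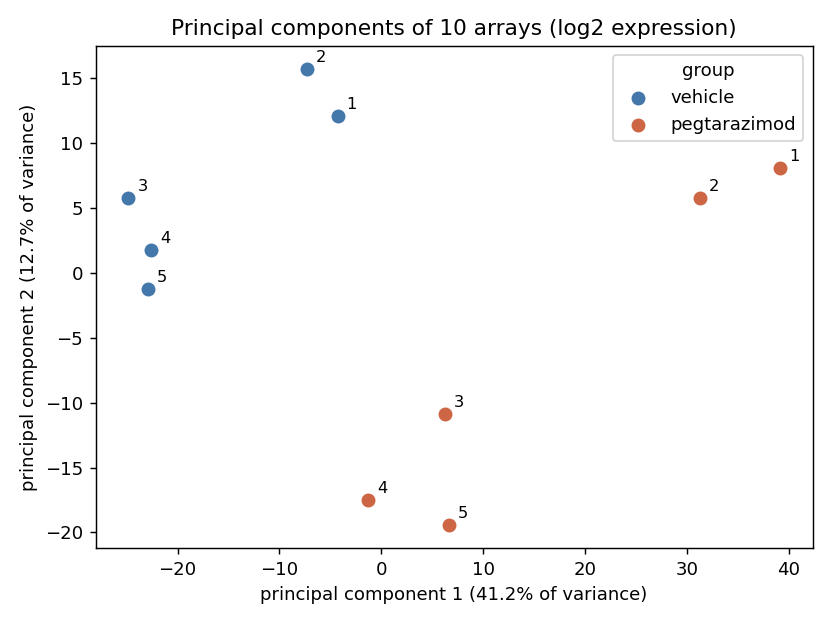
Principal components of the 10 arrays from log2 expression, with the first component (41.2% of the variance) on the x axis and the second (12.7%) on the y axis. Points are arrays, coloured by group and numbered by replicate, and replicates 1 and 2 of each group lie apart from replicates 3 to 5.

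**Figure D2:**
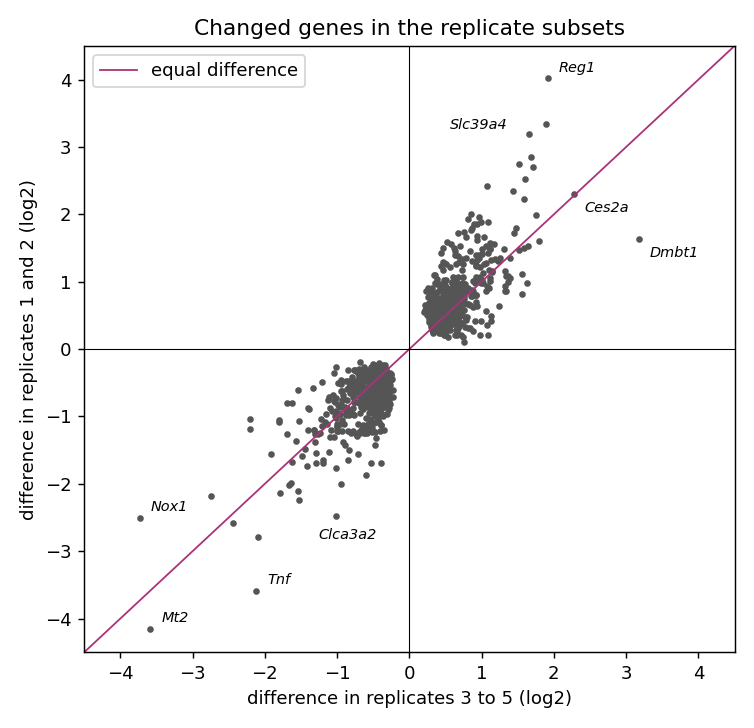
Log2 differences between pegtarazimod and vehicle within replicates 3 to 5 (x axis) and within replicates 1 and 2 (y axis). Each of the 954 points is a gene that changed over all 10 arrays, the line marks equal differences, and all points lie in the quadrants of like sign. Choosing genes by their difference over all 10 arrays favours like signs.

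The 12 largest decreases among changed genes whose groups did not overlap were 3.40-fold to 14.1-fold. Mt2, which encodes a metal-binding metallothionein, fell from 11.91 ± 0.23 to 8.10 ± 0.36 (log2, SD, n = 5 per group; adjusted p = 2.17e-08), and Mt1 fell from 12.13 ± 0.19 to 10.20 ± 0.17 (3.81-fold, adjusted p = 7.76e-07). Nox1, the catalytic subunit of an epithelial NADPH oxidase, fell from 6.51 ± 0.97 to 3.27 ± 0.39 (adjusted p = 3.07e-04), a level below the lower quartile of every array, which lay between 3.75 and 3.82, so its fold and rank are uncertain. Tnf fell from 7.76 ± 0.35 to 5.05 ± 1.24 (adjusted p = 0.00377). The matricellular genes Thbs1 and Ccn1 were 5.72-fold and 3.48-fold lower, the macrophage growth factor gene Csf1 3.40-fold and the Wnt feedback gene Axin2 3.51-fold lower. Ccdc3 (5.65-fold), the stem cell transcription factor gene Ascl2 (3.49-fold) and Sorbs2 (3.42-fold) were also lower. Pla2g2a, which encodes a secreted antimicrobial phospholipase, was 5.19-fold lower (adjusted p = 0.0283), but its adjusted p reached 0.0827 without vehicle 3 and also exceeded 0.05 without vehicle 4, vehicle 5, pegtarazimod 1 or pegtarazimod 2. With an intensity trend and robust priors the adjusted p was 0.109 for Pla2g2a and 0.0515 for Thbs1.

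The 12 largest increases chosen in the same way were 3.49-fold to 6.79-fold. Reg1, which encodes a secreted lectin, had the largest increase (6.79-fold, from 3.52 ± 0.61 to 6.29 ± 1.70, adjusted p = 0.0208). Its vehicle mean lay below the lower quartile of every array, so its fold and rank are uncertain, and it differed by 4.03 in replicates 1 and 2 and by 1.92 in replicates 3 to 5. It was followed by the mucosal scavenger protein gene Dmbt1 (5.91-fold, from 9.03 ± 1.10 to 11.60 ± 0.23, adjusted p = 0.00256), which differed by 1.63 and 3.18 in the subsets and so exceeded Reg1 in replicates 3 to 5. Fabp1 rose from 6.82 ± 0.65 to 9.29 ± 1.21 (adjusted p = 0.00881), the carboxylesterase gene Ces2a from 8.88 ± 0.42 to 11.17 ± 0.32 (4.88-fold, adjusted p = 4.29e-05) and the zinc importer gene Slc39a4 from 7.28 ± 0.45 to 9.55 ± 0.45 (4.83-fold, adjusted p = 1.36e-04). Zg16, a goblet cell lectin gene, was 4.45-fold higher, Clec2h 4.31-fold, and the arginase gene Arg2 4.02-fold higher. The metabolic enzyme genes Cyp2c38 (3.91-fold), Cyp2j9 (3.61-fold), Ugt2a3 (3.60-fold) and Rdh7 (3.49-fold, adjusted p = 0.0238) were also higher. The adjusted p of Reg1 reached 0.0617 and that of Rdh7 0.0725 without vehicle 3, and both also exceeded 0.05 without vehicle 4, vehicle 5 or pegtarazimod 1, as did Rdh7 without pegtarazimod 2. With an intensity trend and robust priors the adjusted p was 0.0879 for Reg1, 0.0513 for Fabp1 and 0.0936 for Rdh7.

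**Figure D3:**
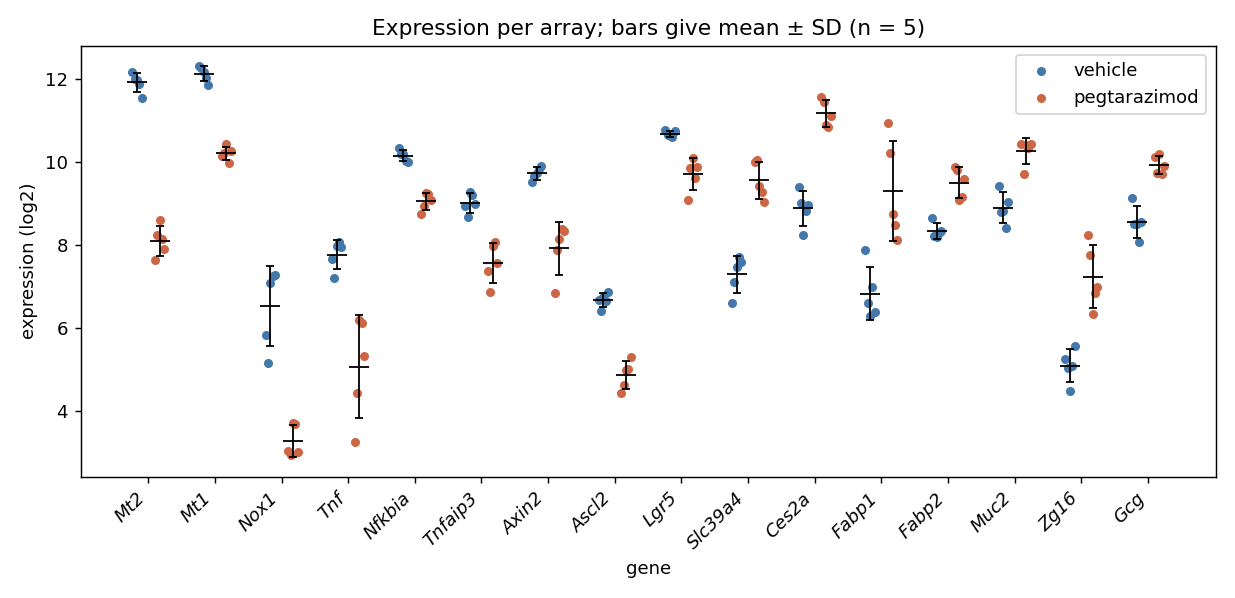
Log2 expression of 16 named genes in each array, grouped by gene on the x axis, with vehicle in blue and pegtarazimod in orange. Points are arrays and black bars the mean ± SD (n = 5), and the groups do not overlap for any of the genes shown.

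Gene lists fixed in advance were compared by camera with a preset correlation of 0.01, adjusted over 35 lists. Of these, 18 were shifted, 8 higher and 10 lower, and all 18 kept the direction of their mean difference within replicates 1 and 2 and within replicates 3 to 5, with 13 passing the test in both. Because the 18 were called over the same arrays, like directions in the subsets are favoured. None of the 18 calls held with an estimated correlation between genes, where the lowest adjusted p was 0.0575. The rotation test fry, which asks whether the genes of a list move on balance one way, called 15 of the 18, all but the enteroendocrine, NRF2 and ribosome biogenesis lists. Of 100 splits of the arrays into groups of 5, the real one included, 5 shifted at least as many lists, and of the 60 splits with 2 arrays of replicates 1 and 2 on each side only the real one did, with 17 lists in the highest other.

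**Figure D4:**
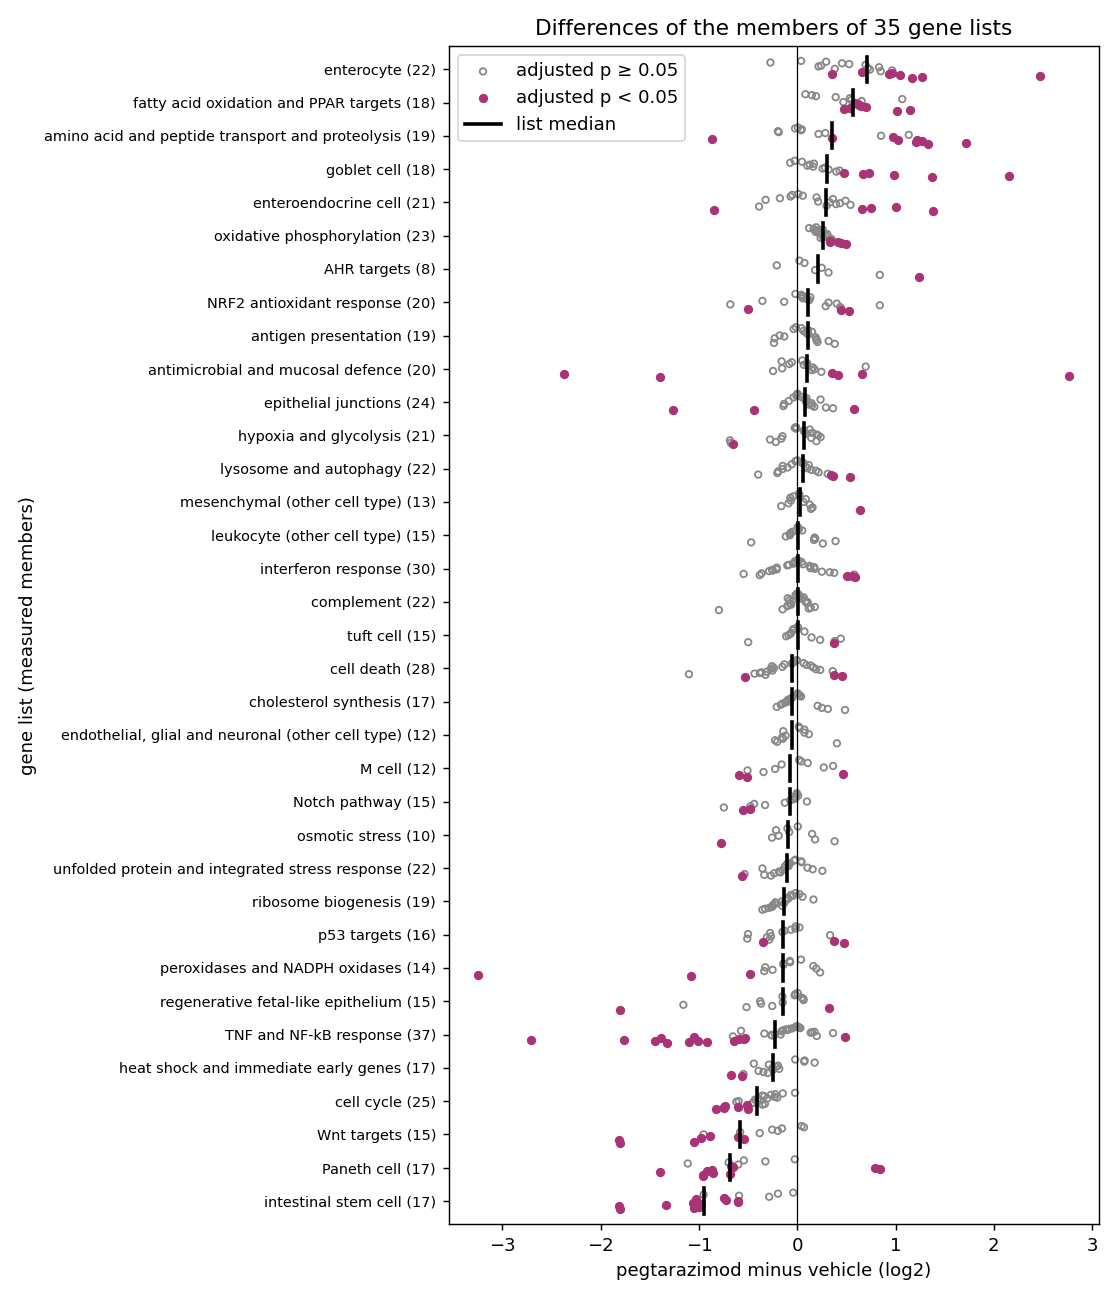
Log2 difference between pegtarazimod and vehicle (x axis) for each measured member of the 35 gene lists (y axis, with the number of members). Filled points passed an adjusted p of 0.05, open points did not, and black bars mark the list medians, which run from -0.95 for the stem cell list to 0.71 for the enterocyte list.

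Genes of the crypt stem cell were lower with pegtarazimod. Of 17 measured stem cell genes 12 fell and none rose, with 15 lower when adjusted over the list alone, and the list mean was -0.87 (-1.02 in replicates 1 and 2, -0.77 in replicates 3 to 5; camera adjusted p = 1.02e-19, adjusted p = 0.0651 with an estimated correlation). Ascl2 fell by 1.80 ± 0.15 (SE) on the log2 scale, Axin2 by 1.81 ± 0.23, Sox9 by 1.05 ± 0.11, Rgmb by 1.00 ± 0.12 and the stem cell receptor gene Lgr5 by 0.98 ± 0.15. Of 15 Wnt targets, 6 of them shared with the stem cell list, 7 fell (10 when adjusted over the list alone), including Sp5 at -0.54, and the list mean was -0.67 (-0.78 and -0.60 in the subsets; camera adjusted p = 1.05e-11, adjusted p = 0.0575 with an estimated correlation). In the Notch pathway 2 of 15 genes fell, Notch2 (-0.55) and Dll1 (-0.48), with 6 lower when adjusted over the list alone and a list mean of -0.21 (camera adjusted p = 0.0041, adjusted p = 0.0645 with an estimated correlation). The median of the Notch list was -0.07, smaller in size than its mean. This list did not pass within replicates 1 and 2 (mean -0.19, adjusted p = 0.110) but did within replicates 3 to 5 (-0.23). The call of Dll1 was lost on leaving out any of 6 arrays, at an adjusted p of up to 0.0752 without vehicle 4. Lfng differed by -0.75 and did not pass (limma adjusted p = 0.0535). It passed with the 2 subsets as a block (0.00129), within replicates 1 and 2 (0.00128) and within replicates 3 to 5 (0.0440).

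Cell cycle genes were also lower, by smaller amounts. Of 25 measured members 7 fell and none rose, 17 fell when adjusted over the list alone, and the list mean was -0.43 (-0.66 in replicates 1 and 2, -0.28 in replicates 3 to 5; camera adjusted p = 3.07e-13, adjusted p = 0.244 with an estimated correlation). The topoisomerase gene Top2a fell by 0.50, the replicative helicase genes Mcm4 and Mcm3 by 0.83 and 0.74, and the replication licensing gene Cdc6 by 0.60. The proliferation marker Mki67 differed by -0.30 and did not pass the test (adjusted p = 0.175), but did within replicates 1 and 2 (-0.65, adjusted p = 0.0116) and not within replicates 3 to 5 (-0.07, 0.824). The adjusted p of Mcm4 was 0.0530 and that of Mcm3 0.0521 without vehicle 3, that of Mcm3 0.0510 without pegtarazimod 2, and Cdc6 exceeded 0.05 on leaving out any of 4 arrays, reaching 0.0659 without pegtarazimod 2. Of 19 ribosome biogenesis genes none passed the limma test over all genes or over the list alone, and 1 had an unadjusted p below 0.05. The mean of that list was -0.13 (camera adjusted p = 0.0216, adjusted p = 0.621 with an estimated correlation, fry adjusted p = 0.349), -0.31 in replicates 1 and 2 and -0.02 in replicates 3 to 5, where it did not pass, and its adjusted p was 0.361 without pegtarazimod 1 and 0.0943 without pegtarazimod 2.

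Enterocyte genes and genes of fat and nutrient handling were higher. Of 22 enterocyte genes 8 rose and none fell, 17 rose when adjusted over the list alone, and the list mean was 0.71 (1.08 in replicates 1 and 2, 0.46 in replicates 3 to 5; camera adjusted p = 1.09e-11, adjusted p = 0.165 with an estimated correlation). Besides Fabp1, the fatty acid binding protein gene Fabp2 rose by 1.17 ± 0.16 (SE), the peptide transporter gene Slc15a1 by 1.27 ± 0.21 and the lipoprotein assembly gene Mttp by 1.04 ± 0.20. The brush border phosphatase gene Alpi differed by 0.97 (adjusted p = 0.0910), by 1.71 in replicates 1 and 2 (adjusted p = 0.00738) and by 0.47 in replicates 3 to 5 (0.453), and passed with the 2 subsets as a block (adjusted p = 0.0280). Of 18 fatty acid oxidation genes and PPAR targets 9 rose (15 when adjusted over the list alone), with a list mean of 0.58 (0.77 and 0.45 in the subsets; camera adjusted p = 2.65e-13, adjusted p = 0.169 with an estimated correlation). Among them were Cpt1a, which controls entry of long-chain fatty acids into mitochondria (1.02), the nuclear receptor gene Ppara (1.15), and the trifunctional protein genes Hadha (0.47) and Hadhb (0.53).

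Of 19 genes of amino acid and peptide transport and proteolysis 8 rose and 1 fell, 12 and 1 when adjusted over the list alone, with a list mean of 0.55 (0.68 and 0.46 in the subsets; camera adjusted p = 2.22e-07, adjusted p = 0.0575 with an estimated correlation). This list shared 4 members with the enterocyte list, including Slc15a1. The amino acid transporter genes Slc7a8, Slc7a7 and Slc7a9 were 3.29-fold, 2.51-fold and 2.31-fold higher. Slc7a5, the catalytic subunit of a large neutral amino acid transporter, was the member that fell (-0.87, adjusted p = 0.0275), and its adjusted p exceeded 0.05 on leaving out any of 5 arrays, reaching 0.0770 without vehicle 3. With an intensity trend and robust priors the limma adjusted p of Slc7a5 was 0.0592. Oxidative phosphorylation genes differed by less. Of 23 measured, 5 rose (16 when adjusted over the list alone), and the list mean was 0.28 (0.36 and 0.23 in the subsets; camera adjusted p = 1.05e-11, adjusted p = 0.0722 with an estimated correlation). The succinate dehydrogenase genes Sdhb and Sdha rose by 0.49 and 0.44 and the cytochrome oxidase genes Cox4i1 and Cox6c by 0.41 and 0.34. Sdha lost its call on leaving out any of 6 arrays, Cox4i1 and Cox6c on leaving out any of 8, with adjusted p of up to 0.0825 and 0.110 without vehicle 3 and 0.112 without pegtarazimod 2, in that order. Quantile normalisation also ended the calls of Cox4i1 and Cox6c (limma adjusted p = 0.0608 and 0.0738), and a block for the replicate number that of Cox6c (0.0659).

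The secretory lineages differed in direction. Of 18 goblet cell genes 6 rose and none fell (8 and 0 when adjusted over the list alone), with a list mean of 0.48 (0.38 and 0.54 in the subsets; camera adjusted p = 2.86e-08, adjusted p = 0.0575 with an estimated correlation). The gel-forming mucin gene Muc2 was 2.58-fold higher, Clca1 1.97-fold, and the mucus protein gene Fcgbp 1.59-fold higher, besides Zg16. Of 17 Paneth cell genes 9 fell and 2 rose, 13 and 2 when adjusted over the list alone (8 and 2 of 16, and 12 and 2, with genes of identical values counted once), with a list mean of -0.57 (-0.58 and -0.56 in the subsets; camera adjusted p = 2.25e-08, adjusted p = 0.136 with an estimated correlation). The defensin genes Defa3 and Defa17 fell by 0.96 each, Defa24 by 0.85 and Defa26 by 0.68. Defa3 and Defa17 had identical values on all arrays and so count as 1 measurement, and near-identical defensin genes can share probes. The lysozyme gene Lyz1 differed by -0.54 (adjusted p = 0.319), and passed with the 2 subsets as a block (adjusted p = 0.01002) and within replicates 3 to 5 (-0.62, 0.0473). The members that rose were the pentraxin genes Mptx1 (0.84) and Mptx2 (0.79), named after their values were seen. Their adjusted p was 0.0511 and 0.0691 without vehicle 3, and that of Mptx2 was 0.0506 without pegtarazimod 1. Within replicates 1 and 2 they differed by 0.42 and 0.36 (adjusted p = 0.304 and 0.425), and within replicates 3 to 5 by 1.13 and 1.08.

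Of 21 enteroendocrine genes 4 rose and 1 fell (5 and 2 when adjusted over the list alone), with a list mean of 0.25 (camera adjusted p = 0.00817, adjusted p = 0.252 with an estimated correlation). The list mean was 0.18 in replicates 1 and 2, where the call was lost (adjusted p = 0.0506), and 0.29 in replicates 3 to 5, and fry gave an adjusted p of 0.0535. The proglucagon gene Gcg rose by 1.38 ± 0.16 (SE), the cholecystokinin gene Cck by 0.75 and Reg4 by 0.66. Neurog3, which encodes the transcription factor of endocrine progenitors, fell by 0.85 ± 0.12. The granin gene Chga differed by 0.33 (adjusted p = 0.281). The tuft, M cell and regenerative epithelium lists did not pass over the 10 arrays, with camera adjusted p of 0.626, 0.335 and 0.248. The regenerative list (mean -0.29) was lower with the 2 subsets as a block (adjusted p = 0.0384), within replicates 3 to 5 (-0.31, 0.0313) and without vehicle 1 (-0.43, 0.0378). Of 15 tuft cell genes 1 rose, Rgs13 (0.38, with both group means below the lower quartile of every array), and the tuft marker Dclk1 differed by 0.38 (adjusted p = 0.178). Of 12 M cell genes Marcksl1 (-0.51) and Pglyrp1 (-0.59) fell and Serpinb6a (0.47) rose, and of 15 regenerative genes Ccn1 fell and Krt19 (0.33) rose. Counts adjusted over each of these 3 lists alone were the same except for 1 lower tuft cell gene. Rgs13, Pglyrp1, Serpinb6a and Krt19 lost their calls on leaving out any of 7, 6, 7 and 9 arrays, with adjusted p of up to 0.109, 0.102, 0.110 and 0.103, without vehicle 3 except for Pglyrp1, without pegtarazimod 2.

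Genes of the NF-kB response were lower in the presence of pegtarazimod. Of 37 measured members 13 fell and 1 rose, 14 and 1 when adjusted over the list alone, with a list mean of -0.45 (-0.46 in replicates 1 and 2, -0.44 in replicates 3 to 5; camera adjusted p = 2.25e-08, adjusted p = 0.0575 with an estimated correlation). The list median was -0.23, smaller in size than the mean. The early response gene Ier3 fell by 1.33 ± 0.12 (SE), the inhibitor gene Nfkbia by 1.10 ± 0.11, the deubiquitinase gene Tnfaip3 by 1.45 ± 0.20 and the subunit gene Nfkb2 by 0.92 ± 0.12, besides Tnf and Csf1. The chemokine genes Cxcl1 (-0.65, adjusted p = 0.143) and Ccl20 (-0.16, adjusted p = 0.585) did not pass the test, but Cxcl1 did with the 2 subsets as a block (adjusted p = 0.0392). The chemokine gene Cx3cl1 rose by 0.48 (adjusted p = 0.0289), and its call was lost on leaving out any of 7 arrays, at an adjusted p of up to 0.0849 without vehicle 3. Of 14 peroxidase and NADPH oxidase genes 3 fell and none rose, also over the list alone, with a list mean of -0.39 (-0.38 and -0.40 in the subsets; camera adjusted p = 0.0129, adjusted p = 0.252 with an estimated correlation). These were Nox1 and 2 genes of its complex, Cyba (-1.09) and Noxo1 (-0.48), the last with an adjusted p of up to 0.0940 without vehicle 3 and a call lost on leaving out any of 5 arrays. The median of this list was -0.14, smaller in size than its mean, to which Nox1 added a difference of -3.24. For 4 of the 14 members both group means lay below the lower quartile of every array.

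Among stress and inflammation lists, the heat shock and immediate early genes were lower, with 2 of 17 that fell (7 when adjusted over the list alone), Klf6 (-0.68) and Atf3 (-0.56), neither of which passed within replicates 1 and 2 (-0.51 and -0.32, adjusted p = 0.145 and 0.254), and a list mean of -0.26 (-0.20 and -0.29 in the subsets; camera adjusted p = 3.76e-05, adjusted p = 0.181 with an estimated correlation). Of 22 genes of the unfolded protein and integrated stress response only Atf3 fell, also over the list alone, with a list mean of -0.13 (camera adjusted p = 0.0216, adjusted p = 0.252 with an estimated correlation). That list mean was -0.27 in replicates 1 and 2 and -0.04 in replicates 3 to 5 (adjusted p = 0.560), and the adjusted p was 0.0875 without vehicle 1 and 0.0819 without vehicle 2. Of 20 NRF2 genes the glutathione transferase gene Gsta4 (0.53) and the thioredoxin gene Txn1 (0.44) rose and the haem oxygenase gene Hmox1 (-0.50) fell, with 6 higher and 1 lower over the list alone and a list mean of 0.13 (camera adjusted p = 0.0243, adjusted p = 0.452 with an estimated correlation, fry adjusted p = 0.119). The NRF2 list mean was 0.16 in replicates 1 and 2 and 0.10 in replicates 3 to 5, where the call was lost (adjusted p = 0.0706). Its adjusted p was 0.0875 without vehicle 3, 0.0797 without pegtarazimod 1 and 0.0789 without pegtarazimod 2. Txn1 and Hmox1 lost their calls on leaving out any of 6 and 7 arrays, with adjusted p of up to 0.0768 without vehicle 4 and 0.111 without vehicle 3. Of 8 AHR targets the cytochrome gene Cyp1a1 rose (1.23, 2.35-fold, adjusted p = 0.0095), with 2 higher over the list alone and a list mean of 0.34 (0.44 and 0.27 in the subsets; camera adjusted p = 0.0273, adjusted p = 0.181 with an estimated correlation, adjusted p = 0.0797 without pegtarazimod 1). Nqo1, a member of both the NRF2 and the AHR list, differed by 0.84 and did not pass (limma adjusted p = 0.115). It passed with the 2 subsets as a block (1.61e-04), within replicates 1 and 2 (0.00620) and within replicates 3 to 5 (0.00605).

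The remaining lists did not pass over the 10 arrays. The interferon list was higher without the dimmest 50% of genes (mean 0.27, adjusted p = 0.0387), and antigen presentation (0.16, 0.0196) and lysosome (0.14, 0.0412) within replicates 1 and 2. No change of complement genes was detectable by limma, with 0 of 22 passing, 1 at an unadjusted p below 0.05 and a camera adjusted p of 0.741. For 6 of the 22, C1qa among them, both group means lay below the lower quartile of every array, where a difference can be missed. The same held for 8 of the 30 interferon response genes. C1qa differed by -0.07 (adjusted p = 0.758), and the myeloperoxidase gene Mpo by -0.07 (adjusted p = 0.799). Of 30 interferon response genes Irf8 (0.59), Irf9 (0.56) and Oas1a (0.51) rose (4 higher and 2 lower over the list alone, camera adjusted p = 0.477). None of 19 antigen presentation genes passed (3 at an unadjusted p below 0.05, camera adjusted p = 0.249). Of 28 cell death genes Casp1 (0.46) and Fas (0.37) rose and Birc3 (-0.53) fell (2 higher and 7 lower over the list alone, camera adjusted p = 0.187), and of 16 p53 targets Perp (0.47) and Fas rose and Btg2 (-0.35) fell (camera adjusted p = 0.187). In the cell death list Bcl2 differed by -1.10 and did not pass (limma adjusted p = 0.0716). It passed with the 2 subsets as a block (0.00343), within replicates 1 and 2 (5.54e-06) and within replicates 3 to 5 (0.0186). Of 24 epithelial junction genes the claudin gene Cldn4 (-1.26) and F11r (-0.44) fell and Cldn15 (0.58) rose (camera adjusted p = 0.477). For the complement, antigen presentation, p53 and junction lists the counts adjusted over the list alone were the same. Of 20 mucosal defence genes 4 rose and 2 fell, among them Reg1, Lypd8 (0.41), Pla2g2a and the angiogenin gene Ang4 (-1.39), with 5 higher and 2 lower over the list alone (camera adjusted p = 0.187). Oas1a, Casp1, Fas, Btg2 and Lypd8 lost their calls on leaving out any of 7, 7, 8, 7 and 5 arrays, with adjusted p of up to 0.0992, 0.0815, 0.110, 0.0701 and 0.0695, and Birc3 and Perp lost theirs without 1 array each, vehicle 5 (0.0513) and vehicle 3 (0.0510).

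In the metabolic lists, the hexokinase gene Hk2 (-0.66) fell among 21 hypoxia and glycolysis genes (camera adjusted p = 0.662), Ctsz (0.54), Atp6v0d1 (0.36) and Ctsa (0.34) rose among 22 lysosome genes (0.249), and Hspa4l (-0.77) fell among 10 osmotic stress genes (0.611). None of 17 cholesterol synthesis genes passed by limma (4 at an unadjusted p below 0.05, camera adjusted p = 0.883). Adjusted over each of these lists alone, 1 osmotic stress gene was also higher and the other counts were the same. Median and mean differed in sign for the cholesterol (-0.05 and 0.02), complement (0.01 and -0.03) and hypoxia (0.07 and -0.06) lists. Hk2, Ctsz, Atp6v0d1 and Ctsa lost their calls on leaving out any of 7, 4, 9 and 9 arrays, with adjusted p of up to 0.0786, 0.0695, 0.111 and 0.126. The lists of markers of other cell types did not pass the test, and their counts were the same when adjusted over each list alone. None of 15 leukocyte genes and none of 12 endothelial, glial and neuronal genes passed by limma (3 and 2 at an unadjusted p below 0.05, camera adjusted p = 0.662 for both). Of 13 mesenchymal genes only Vim rose (0.63, camera adjusted p = 0.512), a gene that epithelial cells can also express, and its adjusted p exceeded 0.05 on leaving out any of 4 arrays, reaching 0.0695 without vehicle 4. For 4 of the 13 mesenchymal genes both group means lay below the lower quartile of every array, where a difference can be missed. The same held for 4 of the 12 endothelial, glial and neuronal genes and 2 of the 15 leukocyte genes.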

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

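The comparison of the treatment effect between replicates 1 and 2 and replicates 3 to 5 was chosen after the results were seen, and the test for single outlying arrays was set before.

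Single arrays lay apart from the other 4 of their group for 8 of the genes named, out of 288 groups of 5 tested, where chance gives about 5% (1 in 20 groups). Reg1 was at 4.59 in vehicle 2 against 3.10 to 3.40 in the other vehicle arrays, and without that array its difference was 3.03 (limma adjusted p = 0.0198). Fabp2 was at 8.64 in vehicle 1 against 8.20 to 8.33, Clca1 at 5.81 in vehicle 4 against 5.26 to 5.40, and Hspa4l at 8.64 in vehicle 1 against 8.83 to 8.88. Muc2 was at 9.71 in pegtarazimod 2 against 10.33 to 10.43, Cpt1a at 8.39 in pegtarazimod 5 against 8.77 to 8.90, and Cxcl1 at 3.71 in pegtarazimod 2 against 4.77 to 5.18. Atp6v0d1 was at 8.42 in pegtarazimod 1 against 8.09 to 8.13, and without that array its difference was 0.30 and its call was lost (adjusted p = 0.111). Fabp2, Muc2, Clca1, Cpt1a and Hspa4l kept their calls without the array in question, and Cxcl1 remained without one.

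The effect of pegtarazimod differed between replicates 1 and 2 and replicates 3 to 5 for 5 genes (limma interaction with Benjamini-Hochberg adjustment). Of 19505 genes, 1493 had an unadjusted p below 0.05 for that difference, where chance gives about 5% of genes. The 5 genes are named after their values were seen. The apoptosis inhibitor gene Bcl2 differed by -1.98 in replicates 1 and 2 and by -0.51 in replicates 3 to 5 (adjusted p of the interaction 0.0200), Clca3a2 by -2.47 and -1.02 (0.0369), and the deoxycytidylate deaminase gene Dctd by -1.34 and -0.02 (0.0357). The histidine decarboxylase gene Hdc differed by 0.10 and -1.34 (0.0369), and the galectin gene Lgals12 by -0.81 and 0.61 (0.0369). Within vehicle alone, 126 genes differed between replicates 1 and 2 and replicates 3 to 5, Hdc among them (replicates 1 and 2 minus 3 to 5 -1.08, adjusted p = 0.00506).

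Of the 2631 probe sets without a gene name here, 60 passed the same threshold, 26 higher and 34 lower with pegtarazimod.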

How the results depend on the processing

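The fits within replicates 1 and 2 and within replicates 3 to 5 were chosen after the results were seen, and the other alternatives before.

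The count of 954 changed genes depended on how the arrays were modelled. With the replicate number as a block (replicate block) it was 1606 (783 higher, 823 lower). Arrays with the same number had deviations from the group means that correlated across genes, which are not independent, by 0.0993 to 0.31, above 0.1 for 4 of 5 numbers, and 4 of 5 vehicle and 4 of 5 pegtarazimod arrays correlated best with their own number, a hint from the data and not from the design, so the numbers were not taken as pairs. With replicates 1 and 2 against 3 to 5 as the block the count was 1820 (877 higher, 943 lower) and included all 954. Leaving out 1 array gave 437 to 1245 changed genes, 230 to 603 higher and 207 to 642 lower (437 without vehicle 3, 498 without vehicle 4, 562 without vehicle 5, 552 without pegtarazimod 1, 522 without pegtarazimod 2, and the highest without pegtarazimod 4). Within replicates 1 and 2, 329 genes changed at least 2-fold, and within replicates 3 to 5, 292 were lower. Quantile normalisation gave 947, median centring 939 (59.1% higher against 51.2%), the filters on dim genes 1061 and 1296, an intensity trend with robust priors 1126, array weights 1057, and the mean over probe sets 953. Of the 954 genes, none that was tested changed sign under these alternatives. No background or detection calls were used, so for genes at the dim end of the arrays a small fold cannot be told from signal near background.

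Of 145 named genes 115 passed the test, and all 115 kept their direction throughout. Of them 78 kept their call without each array in turn, and 61 under every alternative. Quantile normalisation ended 5 calls (Cox4i1, Cox6c, Krt19, Atp6v0d1, Ctsa), the intensity trend with robust priors 9 (Reg1, Fabp1, Rdh7, Thbs1, Pla2g2a, Fas, Slc7a5, Clca3b, Sult1b1), the replicate block 3 (Cox6c, Atp6v0d1, Ctsa) and array weights 1 (Atp6v0d1). The replicate block added 9 calls (Gstm1, Egr1, Lfng, Nqo1, Lyz1, Alpi, Cxcl1, Slc30a1, Bcl2) and the other block these and 4 more (Atf4, Dll4, Nolc1, Hdc). Within replicates 1 and 2, 25 calls were lost, and within replicates 3 to 5, 31, of which 11 were lost in both. Those lost in replicates 1 and 2 alone were Atf3, Btg2, Cck, Clca1, Defa26, F11r, Hmox1, Klf6, Lypd8, Marcksl1, Mptx1, Mptx2, Rgs13, Vim, and in replicates 3 to 5 alone Atp6v0d1, Birc3, Cdc6, Cox4i1, Ctsa, Ctsz, Cx3cl1, Cyp3a25, Gsta4, Hadha, Hadhb, Notch2, Noxo1, Perp, Pglyrp1, Reg4, Slc30a2, Slc30a4, Slc7a5, Sult1b1. Each fit that left out 1 array had equally few arrays, yet the count of changed genes ran from 437 to 1245 with the array left out. Fewer arrays alone therefore do not account for that range. The range does not bear on the calls lost within the subsets, which compared fewer arrays still. The cause of those losses was not tested. Among genes that had not passed, differences turned in sign within replicates 1 and 2 for Mpo (0.0970), Hdc (0.0957) and Lgals12 (-0.81), and Lgals12 ranged from -0.14 to 0.29 on leaving out 1 array.

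The number of shifted lists was 15 to 19 in all alternatives but camera with an estimated correlation, which gave 0 of 35 (lowest adjusted p 0.0575) where fry gave 15, and the 18 lists called kept their direction throughout. The NRF2, stress response, ribosome biogenesis and AHR lists lost their calls without 3, 2, 2 and 1 of the arrays, and the last 3 of these also without the dimmest 50% of genes. Each block changed 1 list call, that of the regenerative epithelium (adjusted p = 0.0126 and 0.0384), which also passed without vehicle 1 (0.0378) and within replicates 3 to 5 (0.0313) and ranged from 0.0126 to 0.747 over all alternatives. The interferon list passed without the dimmest 50% of genes (0.0387), and antigen presentation (0.0196) and lysosome (0.0412) within replicates 1 and 2. Means of lists without a call turned in sign as follows, and the cause was not tested. Without the dimmest 50% of genes, the tuft mean was -0.0571, the leukocyte mean -0.21, the endothelial, glial and neuronal mean 0.13 and the mucosal defence mean -0.23. Without the dimmest 25%, the leukocyte mean was -0.00250 and the endothelial, glial and neuronal mean 0.0142, and with median centring the latter was 0.00439. The cholesterol mean was -0.00211 after quantile normalisation and -0.0262 to 0.0326 on leaving out 1 array, the hypoxia mean -0.17 to 0.0356 and the junction mean -0.00120 to 0.0375, with -0.00526 for junctions within replicates 3 to 5.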

Other observations

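The tests of the replicate subsets and of cell shares, the splits with the subsets balanced, and the 8 gene lists described first, were chosen after the results were seen, and the other tests before.

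Some genes of several enzyme families outside the fixed lists were higher with pegtarazimod, while most members of each family did not pass. Of 77 cytochrome genes of Cyp families 2 to 4, 23 rose and none fell by limma, among them Cyp2c66 (2.83-fold) and Cyp3a25 (2.43-fold), and the list was shifted (camera adjusted p = 2.73e-14, adjusted p = 0.0462 with an estimated correlation, over 8 lists). Of 17 carboxylesterase genes 6 rose, including Ces2a, Ces2e (2.93-fold) and Ces2b (2.33-fold), with a camera adjusted p of 1.09e-09 and an adjusted p of 0.01 with an estimated correlation. Of 31 glucuronosyl and sulfotransferase genes 3 rose, Ugt2a3, Sult1d1 (2.60-fold) and Sult1b1 (2.48-fold), with an adjusted p of 0.0462 with an estimated correlation. Sult1b1 lost its call when any of 5 arrays was left out (vehicle 2 to 5 or pegtarazimod 2, adjusted p of up to 0.0833 without vehicle 3), and within replicates 3 to 5 the adjusted p was 0.0518 for Sult1b1 and 0.0583 for Cyp3a25. These enzymes take part in the handling of drugs and lipids in enterocytes. The 8 lists were written because single members had been seen among the largest differences, so the tests are not independent of that choice. Of 32 targets of the growth-control factors YAP and TEAD, 8 fell and none rose, among them Thbs1, Ccn1, the transcription factor gene Tead2 (2.54-fold) and Ptpn14 (3.13-fold). The other 24 did not pass, including the common target genes Ccn2 (-0.03, adjusted p = 0.948) and Ankrd1 (-0.25, 0.251). Thbs1 and Ccn1 had been seen before this list was written. Members of the Clca family moved apart, since Clca1, a goblet cell product, rose while Clca3a1 (2.58-fold), Clca3a2 (3.03-fold) and Clca3b fell. The last lost its call when any of 7 arrays was left out (the 5 vehicle arrays and pegtarazimod 1 and 2, adjusted p of up to 0.0978 without pegtarazimod 2). The median of this family was -0.50 (camera adjusted p = 0.0189, adjusted p = 0.0473 with an estimated correlation).

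Metallothionein and zinc transporter genes changed in both directions or did not pass. Mt1 and Mt2 fell, Mt3 and Mt4 differed by -0.02 and -0.10 (adjusted p = 0.963 and 0.651), while the importer genes Slc39a4, Slc39a10 (3.04-fold) and Slc39a5 (2.02-fold) rose, and Slc39a6 fell by 0.56. Of the Slc30a genes, Slc30a2, a zinc transporter of Paneth cells, fell by 0.72 and Slc30a4 rose by 0.44. Over 28 zinc transporter and metallothionein genes 4 rose and 4 fell, and that list was not shifted (camera adjusted p = 0.367). Of the 14 importers among them 3 rose and 1 fell, and their list, drawn after Slc39a4 had been seen, gives no test of its own. Slc39a6 and Slc30a4 lost their calls when any of 5 arrays was left out (vehicle 3 to 5 and pegtarazimod 1 and 2, adjusted p of up to 0.0844 and 0.0758 without vehicle 3), and within replicates 3 to 5 the adjusted p was 0.0676 for Slc30a2 and 0.0993 for Slc30a4.

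A lower supply of zinc to the treated cells is a candidate explanation of this zinc pattern, because zinc induces metallothioneins and the exporter gene Slc30a1 through the same factor. Slc30a1 differed by -0.348 ± 0.120 (SE) with an adjusted p of 0.120 (0.0198 to 0.268 over the alternatives, lowest with replicates 1 and 2 against 3 to 5 as the block), so this explanation stays open, as does a different effect of pegtarazimod and PEG on metals in the medium, which was not tested. Fewer crypt cells with more enterocytes was tested with the stem cell and enterocyte list means as covariates. Of the 4 genes Mt1, Mt2, Slc39a4 and Slc39a10, 4 kept their difference. Mt2 differed by -3.55 ± 0.38 (-3.81 ± 0.16 before) and Slc39a10 by 2.83 ± 0.32 (1.60 ± 0.19 before, so its difference became larger). Of the 954 changed genes 176 kept an unadjusted limma p below 0.05. A weaker NF-kB response was tested in the same way with its list mean as covariate, and 4 of 4 were kept. There Mt2 differed by -3.33 ± 0.36, Slc39a10 by 2.74 ± 0.31, and 138 of the 954 were kept. Neither fit decides, because these list means did not overlap between the groups. Their slopes rest on differences within groups, where replicates 1 and 2 stood apart, so both explanations stay open.

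Lower stem cell, Wnt, cell cycle and Paneth lists with higher enterocyte and goblet lists form a pattern that may reflect a shift from crypt to villus cell states. For 6 of the 6 lists the direction was the same in replicates 1 and 2 and in replicates 3 to 5, but each group held 2 and 3 arrays of these subsets, so this test decides nothing about a difference between them. A lower share of stem cells, with transcripts per cell unchanged, could raise every other cell type alike. The Paneth and enterocyte lists did not move alike. The median of the Paneth list lay -1.39 from that of the enterocyte list, with quartiles of -0.88 and -0.49 against 0.36 and 0.96 (genes of identical values counted once). Both directions had been seen before this test was written, and lower transcripts per Paneth cell would give the same values, so it does not decide about cell shares. Other scalings moved none of the list means by more than 0.0276. The deposited values were already normalised by quantiles, so scaling them again could move little, and this test does not decide about scaling between arrays. Whether cells of each type changed in number or in their transcripts per cell was not tested, and the direct effect of pegtarazimod stays open beside it.

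Among 100 of the 126 possible splits of the arrays into 5 and 5, 1 gave as many changed genes as the real one, which was the real split itself, and the highest other count was 35 against 954. For genes changed at least 2-fold it was likewise 1 of 100, with 11 as the highest other count against 155. For both counts no other split drawn came near the real one, and 1 of 100 is the least this test can give. The splits treat the arrays as exchangeable, although replicates 1 and 2 stood apart from the others. For shifted lists by camera with the preset correlation, 5 of 100 splits gave at least the 18 of the real one, with 20 as the highest other count, so chance is not excluded for that count among all splits. The 4 other splits each exchanged 1 array of each group, as did 22 of the splits drawn, and none of the 4 held 2 arrays of replicates 1 and 2 on each side as the real one does. Among all 60 splits balanced in that way only the real one gave 18, with 17 as the highest other count. Because this test was chosen after the first and its margin is 1 list, chance is not taken as excluded for the list count.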
